A study of Arabidopsis thaliana with 9 samples.

How the data were processed

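The series holds mRNA sequencing of root tissue from 2-week-old Arabidopsis plants in 3 genotypes with 3 libraries each: Col-0 wild type, 35S:miR858 and 35S:rMYB83. The growth medium, the planting dates and the number of plants per library are not given in the sources used here. Per the submitters' processing notes, reads passed FastQC and Trimmomatic, TopHat2 2.0.14 and HTSeq, with TAIR10 as the genome build; their settings are not given. The deposited files hold HTSeq counts per gene as whole numbers, 1 file per library, with summary lines for reads that were not assigned. These lines gave reads outside genes at 3.62% to 5.96%, ambiguous reads at 1.72% to 2.08%, and 1.363 to 1.989 non-unique alignments per gene count. The strand setting of the counting is not given, so genes that overlap a partner on the other strand are uncertain. Non-unique alignments were not assigned to genes, so reads common to near-identical paralogs were lost and the counts of these genes are uncertain.

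The files list 28775 loci, of which 28009 matched the reference annotation (TAIR10.1), used here for names, coordinates and sequences. Depth was 9726752 ± 1387513 gene counts in Col-0, 8843447 ± 549842 in 35S:miR858 and 7544620 ± 1932158 in 35S:rMYB83 (SD, n = 3). The nuclear 18S rRNA locus took 9.67 ± 2.03% of the counts in Col-0, 12.6 ± 1.07% in 35S:miR858 and 12.0 ± 2.09% in 35S:rMYB83. The chi-square per degree of freedom between replicates was at least 6.49 times that of counting alone, so the spread between libraries was larger than counting error summed over genes. Intervals and floors printed with counts cover counting error only. Nothing in the labels says that replicates came from separate plant batches, so the p-values measure only the spread between these samples.

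Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with the genotype, TMM scaling (factors 0.93 to 1.117), and a quasi-likelihood F test in 1 fit of all 9 libraries, for 19496 genes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was taken as its size over the square root of F. The comparisons were 35S:miR858 against Col-0, 35S:rMYB83 against Col-0, 35S:rMYB83 against 35S:miR858, and the genes changed in both lines. CPM values use TMM-scaled library sizes. The whole procedure was tested on counts simulated with the depth and gene dispersions of these libraries: for 100 genes changed 2-fold it recovered 63%, 58% and 65% in the 3 comparisons, and for 100 changed 4-fold 91%, 87% and 91%, with 12, 10 and 12 false calls. The changed genes were drawn only from those with a mean of at least 1 CPM. They were fewer than the genes that passed in each real comparison, which shifts the adjusted threshold. These shares therefore do not carry over to the real fits or to genes of lower counts.

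The comparisons, the tests of genes and lists, 22 gene lists, the rules for named genes and most alternatives were fixed before the data were examined. The 22 fixed lists were miR858 target MYBs, secondary wall regulators, secondary wall cellulose, xylan and xylem genes, lignin and phenylpropanoid enzymes, flavonoid enzymes, salicylic acid defence, jasmonate and ethylene response, glucosinolate and camalexin, expansins, auxin response, cytokinin response, iron deficiency, phosphate starvation, root hair, endodermis and suberin, phloem, dividing meristem cells, green shoot tissue, heat shock, hypoxia, touch and wounding, and circadian clock. The heat shock, hypoxia, touch and clock lists were fixed as markers of handling or harvest time. MYB83 was kept out of the tested lists because it is the transgene, and 30 of 325 members had too few counts. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), which asks whether members moved more than other genes. A preset correlation between genes of 0.01 was used, and p was adjusted over the 66 tests. Member counts are given over all genes tested and adjusted over the list alone. After the data were seen, 3 more lists were added: sulphur deficiency, nitrogen starvation and nitrate-induced genes. Their list tests left out the 8 members whose values had been seen before, with p adjusted over 9 tests.

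Named genes were chosen by rule: MYB83, MIR858 loci and the target MYBs; per comparison with wild type the 6 higher and 6 lower genes with the largest fold, a mean of at least 1 CPM and groups that did not overlap. For each list and comparison up to 4 members with the smallest adjusted p were eligible, or the 1 with the smallest p where none passed, and 4 per direction class of genes changed in both lines. The direct comparison used 4 higher and 4 lower. Some of these genes are not printed, most of them genes whose call a single left-out library ended. Members of the added lists, and KNAT7 in 35S:miR858, were named after their values were seen. A fold against a group with 0 counts was bounded with a floor of 3 counts over the group, and with 1 to 3 counts it carries a 95% counting interval.

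Fold changes of the lines share the 3 wild-type libraries, so their covariance was compared with 40 simulations of unchanged groups against these libraries. Genes with a predicted miR858 site (penalty of at most 5) were compared with 10000 random lists matched for expression. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in 3 libraries, a fit of only the 2 groups compared, a replicate block, each library left out, camera with an estimated correlation, and fry, which rotates residuals and asks whether members moved at all, in 1 direction or mixed. Added after the data were seen were the omission of the 2 libraries with the most green shoot transcripts together, a green shoot marker score as covariate (mean log2 CPM of 20 markers), and library totals without scaling. All other splits of the 6 libraries of each comparison (10 splits each) and 100 drawn assignments of the 9 libraries were also run. Deviations from the group mean correlated at 0.55, 0.24 and 0.14 between libraries of the same replicate number in Col-0 and 35S:rMYB83, all over 0.1. For that comparison results with the replicate block are therefore also given, while its main fit has no block. Such a pairing comes from the data and not from the labels, and 4 of the 6 libraries correlated best with their own number. The 0.55 belonged to the 2 libraries with the most green shoot transcripts. Col-0 replicate 3 and 35S:rMYB83 replicate 2, of different number, correlated at 0.46. With groups of only 3, no test of single outlying samples was run. Figures and summaries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.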

Results

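Roots of 2-week-old Arabidopsis plants of 3 genotypes were profiled: Col-0 wild type, plants that overexpress the microRNA miR858 (35S:miR858) and plants that overexpress a miR858-resistant form of the secondary wall regulator MYB83 (35S:rMYB83). No label names a nematode infection, so all values describe roots for which no infection is stated. Total gene counts were 10400372, 10648857 and 8131026 for the 3 Col-0 libraries, 8658776, 8409713 and 9461852 for 35S:miR858, and 5313656, 8678440 and 8641763 for 35S:rMYB83. The first principal component of log2 CPM (counts scaled to library size) held 47.6% of the variance and placed Col-0 between -72.7 and -41.3 and the libraries of both overexpression lines between 15.1 and 43.3. Pearson correlations lay between 0.958 and 0.983 within genotypes and between 0.891 and 0.971 across them. The 20 markers of green shoot tissue took 0.46% of the gene counts in Col-0 replicate 1 (95% interval 0.455 to 0.464) and 0.809% in 35S:rMYB83 replicate 1 (0.801 to 0.816), against 0.0675% to 0.205% in the other libraries.

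MYB83 transcripts, which encode a MYB factor that switches on secondary wall synthesis in xylem, stood at 1.28 ± 0.78 CPM in Col-0 (SD, n = 3), 1.53 ± 0.0271 CPM in 35S:miR858 and 112 ± 19.9 CPM in 35S:rMYB83. In 35S:rMYB83 the gene rose over wild type by a log2 fold change of 6.39 (SE 0.28, adjusted p = 5.16e-06), and reads of the introduced and the native copy were counted together at this locus. Between 35S:miR858 and wild type the MYB83 value was 0.22 (SE 0.38, adjusted p = 0.723). The precursor of miR858a, a microRNA that guides cleavage of MYB transcripts, had 120, 200 and 227 counts in the 3 libraries of 35S:miR858 and 0 in each of the other 6. This was at least 222-fold higher than in wild type against a floor of 3 counts over the group (adjusted p = 0.000215). The mature miRNA was not measured by these mRNA libraries.

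**Figure D1:**
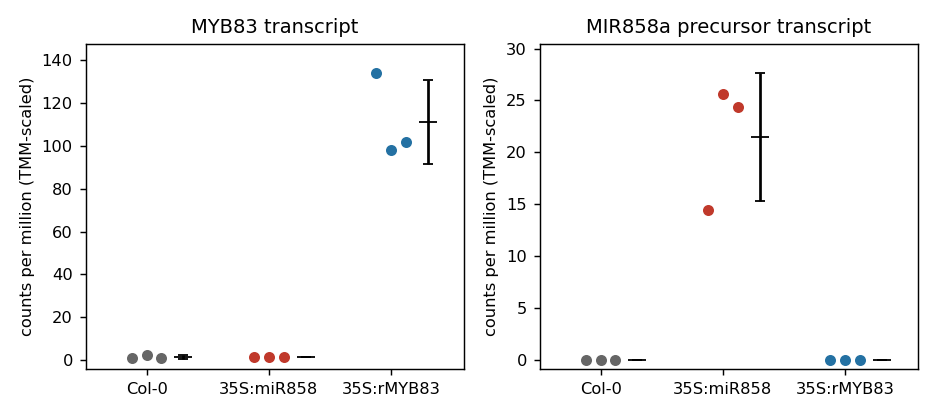
MYB83 and MIR858a transcripts in CPM in each of the 9 root libraries; the dash marks the group mean and the bar the SD (n = 3).

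The MYB83 gene lies on chromosome 3 from 2576444 to 2578276 on the minus strand and has 2 exons. Its predicted miR858 site, CAGGTAGAACAGACAACGAGA, lies in the coding part of exon 2 (2577626 to 2577646) and pairs with TTTCGTTGTCTGTTCGACCTT, the mature miR858a, with 2 mismatches and 1 G:U wobble. The sequence change that makes the introduced copy resistant is not given in the sources used here.

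**Figure D2:**
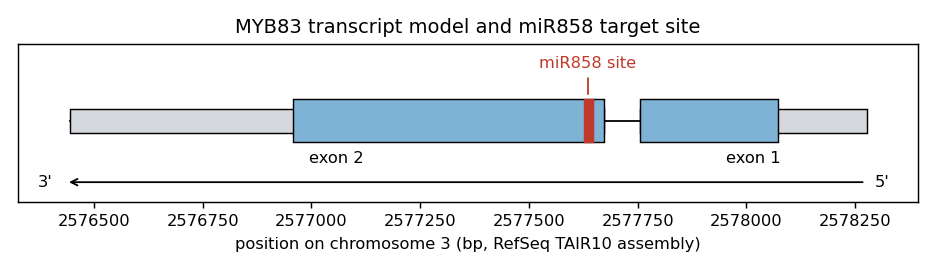
Exons of MYB83 on chromosome 3 with the coding part and the predicted miR858 site.

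In 35S:miR858 many genes that build and regulate cell walls had lower transcript levels than in wild type. Of 23 tested secondary wall regulators, 12 fell in 35S:miR858 against wild type and 11 did not pass (14 fell adjusted over the list alone). The list mean was -0.68 (adjusted p = 0.0012, and adjusted p = 0.68 with an estimated correlation). MYB63, an activator of lignin genes, fell by 1.60 on the log2 scale (SE 0.24, adjusted p = 0.0012), and MYB43, a MYB factor of fibre and vessel walls, fell by 1.09 (SE 0.17, adjusted p = 0.0016). SND3, a NAC factor of fibre walls, dropped from 21.1 ± 4.81 to 7.39 ± 1.11 CPM, and MYB69, another wall MYB factor, from 10.1 ± 1.25 to 3.06 ± 1.14 CPM (SD, n = 3; adjusted p = 0.00116 and 0.00122). Of 23 genes for secondary wall cellulose, xylan and xylem, 6 fell and 17 did not pass (6 fell adjusted over the list alone). Their list mean was -0.52 (adjusted p = 0.029, and adjusted p = 0.99 with an estimated correlation). Those that fell included the xylem cell death nuclease BFN1 (log2 -3.31, adjusted p = 2.55e-05), the irregular xylem gene IRX15-L (-1.98, 0.000586) and GUX2, which adds glucuronic acid to xylan (-1.70, 0.00113). Among 22 lignin and phenylpropanoid enzymes, 10 fell, 2 rose and 10 did not pass (10 fell and 2 rose adjusted over the list alone). Over the whole list the mean was -0.31 (adjusted p = 0.029, and adjusted p = 0.99 with an estimated correlation). The coumarate ligase 4CL1 dropped from 415 ± 88.1 to 125 ± 6.64 CPM (SD, n = 3; adjusted p = 7.46e-05). The monolignol enzyme CAD5 dropped from 146 ± 25.1 to 53.3 ± 6.79 CPM (SD, n = 3; SE of log2 0.15, adjusted p = 0.000174), and CCR1 of the same pathway fell from 154 ± 24.5 CPM (SD, n = 3; SE of log2 0.12, adjusted p = 0.000346). Without Col-0 replicate 1 the cellulose, xylan and xylem genes that fell numbered 14, and without Col-0 replicate 2 or Col-0 replicate 3 the lignin enzymes that fell numbered 6. The list test of the cellulose, xylan and xylem genes gave adjusted p = 0.263 without Col-0 replicate 2 and 0.152 without Col-0 replicate 3, and that of the lignin enzymes gave 0.105, 0.152 and 0.0551 without Col-0 replicate 2, Col-0 replicate 3 and 35S:miR858 replicate 1. With fry in 1 direction these 2 lists had adjusted p = 0.20 and 0.12. With the green covariate the lignin list had 0.0547, and 4 lignin enzymes rose and 10 fell.

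In 35S:miR858 7 flavonoid enzymes and 5 expansins were also lower than in wild type. Of 13 tested flavonoid enzymes, 7 fell and 6 did not pass (7 fell adjusted over the list alone). Mean change over the list was -1.14 (adjusted p = 0.0016, and adjusted p = 0.80 with an estimated correlation). Flavonol synthase FLS1 dropped from 57.3 ± 8.82 to 15.9 ± 12.5 CPM (SD, n = 3; log2 -1.85, adjusted p = 0.0113). The flavonoid-linked coumarate ligase 4CL3 fell by 2.00 and the flavonol glucosyltransferase UGT78D2 by 1.02 (adjusted p = 0.00392 and 0.00858). Of 13 tested expansins, which loosen cell walls, 5 fell, 1 rose and 7 did not pass (7 fell and 1 rose adjusted over the list alone). The mean over these genes was -0.90 (adjusted p = 0.029, and adjusted p = 0.57 with an estimated correlation). EXPB3 dropped from 318 ± 59.0 to 48.0 ± 5.60 CPM (SD, n = 3), EXPA4 from 322 ± 26.1 to 88.2 ± 9.72 CPM, and EXPA6 fell by 1.93 on the log2 scale (adjusted p = 3.47e-05, 4.11e-05 and 9.95e-06). Without 35S:miR858 replicate 3 the flavonoid enzymes that fell numbered 4. Without Col-0 replicate 2 the expansin list had an adjusted p of 0.105, and the expansins that rose numbered 2. On library totals the expansin list had 0.0844.

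Among the 4 tested miR858 target MYB genes, MYB42, a wall MYB factor, fell from 4.93 ± 1.80 to 1.61 ± 0.0519 CPM (SD, n = 3; log2 -1.60, adjusted p = 0.0095) and 3 did not pass (3 fell adjusted over the list alone; list adjusted p = 0.27, and 0.006 with fry in 1 direction). The flavonol regulator MYB12 had a log2 value of -0.73 (SE 0.30, adjusted p = 0.101), the growth-related MYB13 -0.33 (SE 0.14, adjusted p = 0.108) and the lignin-related MYB20 0.10 (SE 0.23, adjusted p = 0.819). MYB20 and MYB42 also belong to the secondary wall regulators, so the 2 lists are not separate. MYB63, MYB85 and MYB32 of the regulators have predicted miR858 sites too, at penalties of 4, 5 and 5. Flavonol regulators MYB11 and MYB111 had too few counts to be tested, with 6, 13 and 4 against 1, 1 and 0 counts for MYB11 (9.45 times lower, interval 2.34 to 82.7) and 2, 3 and 0 against 0, 0 and 1 for MYB111 (4.11 times lower, interval 0.46 to 194).

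Touch and wounding genes were higher in 35S:miR858, where 5 of 6 rose and 1 did not pass (6 rose adjusted over the list alone). List-wide the mean came to 1.76 (adjusted p = 0.0038, and adjusted p = 0.79 with an estimated correlation). The calmodulin-like touch gene TCH3 rose from 27.1 ± 8.97 to 116 ± 45.8 CPM and the zinc finger gene ZAT10 from 56.6 ± 30.9 to 209 ± 76.1 CPM (SD, n = 3; adjusted p = 0.0012 and 0.00624). Heat shock genes had 3 of 5 members that fell and 2 that did not pass (3 fell adjusted over the list alone). Their list mean was -1.09 (adjusted p = 0.029, and adjusted p = 0.79 with an estimated correlation), and those that fell included the heat shock regulator HSFA2 (-2.65, adjusted p = 0.00212) and the chaperone HSP101 (-1.04, adjusted p = 0.000627). Clock genes moved both ways, with 5 that fell, 4 that rose and 2 of 11 that did not pass (6 fell and 4 rose adjusted over the list alone; list adjusted p = 0.52). The morning gene LHY fell by 2.46, the day gene PRR9 by 2.83 and the clock output gene GI by 1.44 on the log2 scale (adjusted p = 0.00159, 0.00253 and 0.000473), while the evening gene LUX rose by 0.81 (adjusted p = 0.00242). Without Col-0 replicate 2, Col-0 replicate 3, 35S:miR858 replicate 1 and 35S:miR858 replicate 2, the touch genes that rose numbered 3, 2, 3 and 2, and the heat shock list had adjusted p = 0.0675 and 0.0938 without Col-0 replicate 1 and Col-0 replicate 2. It had 0.0766 on library totals and 0.0735 without Col-0 replicate 1 and 35S:rMYB83 replicate 1 together.

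None of the other lists passed camera with the preset correlation in 35S:miR858. Phosphate starvation genes had 4 of 9 that fell (5 adjusted over the list alone; list adjusted p = 0.052). The list passed with RLE size factors (0.0467), no filter (0.0311), only the 2 groups (0.0376), fry in 1 direction (0.016) and without 35S:miR858 replicate 1 (0.0344). The membrane lipid gene MGD3 stood at a log2 of -4.14 and the phosphate transporter PHT1;1 at -0.61 (adjusted p = 0.000788 and 0.00771). Glucosinolate and camalexin genes had 3 that rose and 3 that fell of 21 (3 and 4 adjusted over the list alone; list adjusted p = 0.68). CYP71A12 of camalexin synthesis fell by 6.31 on the log2 scale (SE 0.40, adjusted p = 2.58e-05). Among endodermis and suberin genes 5 fell and 1 rose of 15 (5 and 1 adjusted over the list alone; list adjusted p = 0.68). The suberin alcohol reductases FAR4 and FAR1 stood at -2.25 and -1.78 (adjusted p = 0.00034 and 0.00124). Phloem genes had 4 that fell and 2 that rose of 13 (5 and 2 adjusted over the list alone; list adjusted p = 0.52), among them the sucrose loader SUC2 (-1.12, adjusted p = 0.00227). Jasmonate and ethylene genes had 4 that rose and 1 that fell of 19 (4 and 1 adjusted over the list alone; list adjusted p = 0.17). The defence gene PR4 rose from 116 ± 39.1 to 390 ± 56.6 CPM (SD, n = 3; adjusted p = 0.000907). Salicylic acid genes had 3 that rose and 1 that fell of 12 (3 and 3 adjusted over the list alone; list adjusted p = 0.30), with the immune regulator SAG101 at 0.83 (adjusted p = 0.00107), and DESeq2 called 3 that fell. Iron deficiency genes had 2 that rose and 2 that fell of 15 (2 and 2 adjusted over the list alone; list adjusted p = 0.78). The ferric reductase FRO2 stood at 1.72 and the coumarin enzyme F6'H1 at -1.15 (adjusted p = 0.00837 and 0.000385). Cytokinin genes had 2 of 7 that rose (2 adjusted over the list alone; list adjusted p = 0.43) with the response regulator ARR8 at 0.47 (adjusted p = 0.00716). Auxin genes had 1 of 9 that fell (1 adjusted over the list alone; list adjusted p = 0.81), GH3.1 of auxin conjugation at -1.20 (adjusted p = 0.00371). Hypoxia genes had 2 of 8 that fell (3 adjusted over the list alone; list adjusted p = 0.16) and root hair genes 1 of 14 (0 adjusted over the list alone; list adjusted p = 0.89), in edgeR. For dividing meristem cells and green shoot tissue no member passed the edgeR test, and the members with the smallest p were the cyclin CYCA1;1 (-0.51, adjusted p = 0.0821) and the antenna gene LHCB2.1 (-1.76, adjusted p = 0.253), with list adjusted p of 0.78 and 0.90. At an unadjusted p under 0.05 edgeR gave 2 and 0 members of these lists, and DESeq2 called 0 in both. With 1 library left out, the genes that fell ranged from 0 to 6 for hypoxia, 0 to 5 for root hair, 1 to 5 for phloem, 2 to 5 for glucosinolate and camalexin, 0 to 3 for salicylic acid, 1 to 2 for iron deficiency and for auxin, and 0 to 1 for jasmonate and for meristem. The genes that rose ranged from 3 to 7 for glucosinolate and camalexin, 2 to 6 for jasmonate, 1 to 4 for salicylic acid and for iron deficiency, 1 to 2 for cytokinin, and 0 to 2 for phloem and for endodermis and suberin. For phosphate starvation and root hair they ranged from 0 to 1. Without 35S:miR858 replicate 1, 6 hypoxia and 5 root hair genes fell, and the hypoxia list had adjusted p = 0.000826. The jasmonate list had 0.0439 without Col-0 replicate 1, 0.00241 without 35S:miR858 replicate 3 and 0.0269 on library totals. The green shoot list had 0.0107 without Col-0 replicate 1 and 35S:rMYB83 replicate 1 together. With the green covariate 4 endodermis and suberin genes rose and 5 fell.

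In all, 4900 of 19496 tested genes (25.1%) changed in 35S:miR858 against wild type, 2271 higher and 2629 lower, with 665 and 1272 at a fitted fold of at least 2. The genes with the largest falls included NRT2.5, a high-affinity nitrate transporter, which dropped from 178 ± 40.9 CPM (SD, n = 3) to 0 counts, at least 1500-fold lower against the floor over the group (adjusted p = 1.22e-05). The ammonium transporter gene AMT1;5 was at least 213-fold lower, the cupin gene AT5G38910 at least 142-fold and the sulphur-starvation glucosidase BGLU28 at least 72.6-fold (adjusted p = 0.00091, 0.000118 and 0.00224). The protein phosphatase gene AT4G32950 was 746 times lower (counting interval 255 to 3620) and AT3G44840, a methyltransferase gene, at least 55.9-fold lower (adjusted p = 9.95e-06 and 0.000362). The genes with the largest rises beside MIR858a included the dwarfing AP2 factor DDF1 (log2 5.04, adjusted p = 0.0044). DDF1 was uneven, with 7.44, 12.5 and 0.753 CPM in 35S:miR858 against 0.259, 0.0905 and 0.241 in Col-0. They also included the zinc finger gene ZAT7 (30.4 times higher, interval 7.99 to 258, adjusted p = 0.00203) and AT5G63250, for a carbohydrate-binding X8 domain protein (log2 4.19, adjusted p = 4.15e-05). For 40.6% of tested genes the 3 libraries of each group did not overlap, where chance gives 10%. Scaling by library totals alone moved the median of all genes by -0.144 and gave 1355 higher and 4148 lower, and the number higher was 1493 without 35S:miR858 replicate 2.

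Roots with more MYB83 had a mixed picture at secondary wall genes. Of 23 tested regulators, 1 rose, 4 fell and 18 did not pass in 35S:rMYB83 against wild type (5 rose and 7 fell adjusted over the list alone; list adjusted p = 0.89). KNAT7, a homeobox regulator of secondary walls, rose from 32.3 ± 5.59 to 56.1 ± 7.28 CPM (SD, n = 3; log2 0.80, adjusted p = 0.00627). MYB69 of wall formation fell by 1.73, the xylem repressor XND1 by 1.28 and VNI2, a repressor of vessel formation, by 0.62 on the log2 scale (adjusted p = 0.00214, 0.00986 and 0.00692). Of 23 cellulose, xylan and xylem genes, 3 rose, 4 fell and 16 did not pass (3 rose and 5 fell adjusted over the list alone; list adjusted p = 0.97). The xylan gene FRA8 rose from 62.2 ± 8.52 to 120 ± 5.04 CPM (SD, n = 3; adjusted p = 0.00338), and the nuclease gene BFN1 fell by 2.96 on the log2 scale (adjusted p = 4.64e-05). IRX15-L had 17.8, 19.4 and 18.4 CPM against 32.5, 76 and 54.8 in Col-0. GUX2 had 7.95, 9.54 and 6.81 against 11.4, 19.3 and 18.6. The regulator SND3 had 9.46, 13 and 8.06 against 16.3, 25.9 and 21.2. For these 3 genes every library of both lines thus lay below all 3 of Col-0, while MYB63 and MYB43 overlapped with Col-0 here. Of all tested genes 34% had no overlap between 35S:rMYB83 and Col-0. The 3 genes were named for their falls in 35S:miR858 against the same Col-0 libraries. Of 22 lignin enzymes, 3 rose, 3 fell and 16 did not pass (6 rose and 3 fell adjusted over the list alone; list adjusted p = 0.68). Lignin peroxidase PRX72 stood at 1.02 and 4CL1 and CAD5 at -0.71 and -0.72 (adjusted p = 0.00957, 0.00977 and 0.00964). For the regulators and the cellulose genes the list means were -0.10 and -0.12 and the medians 0.07 and 0.08. Without Col-0 replicate 2 or Col-0 replicate 3 the regulators that rose numbered 2. The cellulose, xylan and xylem genes that fell numbered 7 without Col-0 replicate 1 and 2 without Col-0 replicate 2, 35S:rMYB83 replicate 1 or 35S:rMYB83 replicate 3, and those that rose numbered 1 without 35S:rMYB83 replicate 2. The lignin enzymes that rose numbered 1 without 35S:rMYB83 replicate 1 or 35S:rMYB83 replicate 2, and those that fell numbered 6 without Col-0 replicate 1. With the replicate number as a block 5 lignin enzymes rose. DESeq2 called 3 regulators and 6 lignin enzymes that rose.

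Of the 4 tested miR858 targets in 35S:rMYB83, MYB12 rose from 12.2 ± 1.11 to 25.1 ± 8.24 CPM (SD, n = 3; log2 1.03, SE 0.28, adjusted p = 0.0324) and 3 did not pass (2 rose adjusted over the list alone; list adjusted p = 0.66). The call for MYB12 was lost without any 1 of Col-0 replicate 1, Col-0 replicate 2, Col-0 replicate 3, 35S:rMYB83 replicate 1 and 35S:rMYB83 replicate 2, with adjusted p over all left-out libraries from 0.0103 to 0.111. Log2 values were -0.30 for MYB13, 0.64 for MYB20 and -0.33 for MYB42 (adjusted p = 0.174, 0.0892 and 0.549). Counts were 3, 3 and 2 for MYB11 and 2, 0 and 0 for MYB111.

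Heat shock and touch genes passed the list test in 35S:rMYB83 against wild type. Of 5 heat shock genes, 3 fell and 2 did not pass (5 fell adjusted over the list alone). Over the whole list the mean was -1.25 (adjusted p = 0.0054, and adjusted p = 0.68 with an estimated correlation), with HSFA2 at -2.31 and HSP101 at -0.78 (adjusted p = 0.00628 and 0.00427). Of 6 touch genes, 1 rose and 5 did not pass (2 rose adjusted over the list alone). Across the list the mean was 1.07 (adjusted p = 0.032, and adjusted p = 0.94 with an estimated correlation). Without Col-0 replicate 2, Col-0 replicate 3, 35S:rMYB83 replicate 1 and 35S:rMYB83 replicate 2 the touch list had adjusted p = 0.164, 0.110, 0.0628 and 0.0525. It had 0.0783 with the green covariate and 0.27 with fry in 1 direction. Clock genes had 4 that rose and 4 that fell of 11 (4 and 5 adjusted over the list alone; list adjusted p = 0.89). The evening genes ELF4 and LUX stood at 1.81 and 0.91 and the morning gene LHY at -1.94 (adjusted p = 0.000968, 0.00221 and 0.00755). The clock genes that fell numbered 1 without Col-0 replicate 2, Col-0 replicate 3 or 35S:rMYB83 replicate 2, and 2 without 35S:rMYB83 replicate 3. The touch gene TCH3 stood at 1.06 (adjusted p = 0.0435). Its call was lost without any 1 of Col-0 replicate 2, Col-0 replicate 3 and the 3 libraries of 35S:rMYB83 (adjusted p up to 0.159), and with the replicate number as a block (adjusted p = 0.0685). The touch genes that rose numbered 5 without Col-0 replicate 1 and 0 in the other left-out fits.

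No other list passed camera with the preset correlation in 35S:rMYB83 in the fit of all 9 libraries without a block. Expansins had 3 of 13 that fell (3 adjusted over the list alone; list adjusted p = 0.23, and 0.042 with fry in 1 direction), with EXPA6 at -0.79 and EXPB3 at -1.31 (adjusted p = 0.000766 and 0.00147). Flavonoid enzymes had 1 of 13 that rose (1 adjusted over the list alone; list mean 0.51, adjusted p = 0.08, and adjusted p = 0.99 with an estimated correlation). With the replicate number as a block 3 rose and the list had adjusted p = 0.0354. It had 0.0288 with only the 2 groups, 0.00634 without 35S:rMYB83 replicate 3 and 0.03 on library totals. Endodermis and suberin genes had 4 of 15 that fell (6 adjusted over the list alone; list adjusted p = 0.17). The suberin genes FAR4, FAR1 and KCS2 stood at -1.65, -1.69 and -1.07 (adjusted p = 0.00248, 0.00255 and 0.0118). Phloem genes had 3 that fell and 1 that rose of 13 (4 and 1 adjusted over the list alone; list adjusted p = 0.17), among them SUC2 at -1.05 and the protein transport gene FTIP1 at -0.57 (adjusted p = 0.00524 and 0.0101). Glucosinolate and camalexin genes had 2 that fell and 1 that rose of 21 (2 and 1 adjusted over the list alone; list adjusted p = 0.97). CYP71A12 stood at -4.71, the indole glucosinolate gene CYP81F2 at -2.23 and CYP79B3 of the same pathway at 0.91 (adjusted p = 7.9e-05, 0.00035 and 0.0092). Phosphate starvation genes had 3 that rose and 2 that fell of 9 (3 and 2 adjusted over the list alone; list adjusted p = 0.62). Auxin genes had 2 of 9 that fell (2 adjusted over the list alone; list adjusted p = 0.47), with GH3.5 of auxin conjugation at -0.74 (adjusted p = 0.00713). Of jasmonate and ethylene, cytokinin and iron deficiency genes 1 of 19, 1 of 7 and 1 of 15 rose (1, 1 and 0 adjusted over the list alone; list adjusted p = 0.28, 0.31 and 0.31). PR4 stood at 1.19 and ARR8 at 0.50 (adjusted p = 0.00961 and 0.0081). In salicylic acid, root hair, meristem, hypoxia and green shoot lists no member passed the edgeR test (list adjusted p = 0.68, 0.56, 0.68, 0.89 and 0.059). The smallest p belonged to the salicylic acid exporter EDS5 (-0.64, adjusted p = 0.0797), the root hair gene PRP1 (-0.76, 0.136), the cyclin CYCB1;1 (0.30, 0.394), the haemoglobin HB1 (1.25, 0.0513) and the antenna gene LHCA3 (1.02, 0.341). At an unadjusted p under 0.05 edgeR gave 3, 1, 0, 1 and 0 members of these 5 lists, and DESeq2 called 0, 0, 0, 1 and 0. The mean of the 20 green shoot markers was 1.13 higher on the log2 scale in 35S:rMYB83 than in wild type (adjusted p = 0.0125 with the replicate number as a block, and adjusted p = 0.99 with an estimated correlation). It depended on single libraries: relative to the Col-0 mean the 3 libraries stood at 2.90, -0.14 and 0.62, and without 35S:rMYB83 replicate 1 the difference was 0.24. Without Col-0 replicate 1 it was 2.09, and without Col-0 replicate 3 0.36. The list passed without Col-0 replicate 1, 35S:rMYB83 replicate 2 and 35S:rMYB83 replicate 3 (adjusted p = 0.000405, 0.0032 and 0.0224) and without Col-0 replicate 1 and 35S:rMYB83 replicate 1 together (0.00295). It also passed with no filter (0.034), with the CPM filter (0.0499) and on library totals (0.00991). Without Col-0 replicate 1 the suberin and iron deficiency lists had 0.00575 and 0.0439, and without it and 35S:rMYB83 replicate 1 together the suberin and glucosinolate lists had 0.00935 and 0.0496. DESeq2 called 2 flavonoid enzymes that rose and 2 jasmonate genes that fell. With the block HB1 rose (adjusted p = 0.00504), 3 jasmonate and 2 glucosinolate genes rose, 1 jasmonate gene fell, 1 suberin gene rose, and 0 iron deficiency genes rose. Of phosphate starvation genes that rose, 0 were left without Col-0 replicate 2, Col-0 replicate 3, 35S:rMYB83 replicate 1 or 35S:rMYB83 replicate 2, and without Col-0 replicate 1 the glucosinolate genes that rose numbered 8, the jasmonate genes that rose 4 and the suberin genes that fell 7. With 1 library left out, salicylic acid genes that fell numbered 0 to 3, phosphate starvation genes that fell 0 to 2, auxin genes that fell 1 to 2 and cytokinin genes that rose 1 to 2. The flavonoid, iron deficiency and phloem genes that rose, and jasmonate genes that fell, numbered 0 to 1, as did expansins and hypoxia genes that rose.

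In all, 3203 of 19496 genes (16.4%) changed in 35S:rMYB83 against wild type, 1306 higher and 1897 lower, with 411 and 889 at a fitted fold of at least 2. Beside MYB83 the genes with the largest rises included the CCT motif gene AT2G33350, at least 43.5-fold higher, the sugar transporter family gene AT1G34580, 111 times higher (counting interval 19.4 to 4440, with 9.84, 1.83 and 1.48 CPM in the 3 libraries), and the seed storage albumin gene SESA4, 67.6 times higher (22.7 to 332), with adjusted p = 0.00085, 0.00552 and 0.000722. The largest falls included NRT2.5, 1970 times lower (545 to 16300, adjusted p = 2.09e-05), and the RWP-RK factor gene AT3G59580, 286 times lower (97.5 to 1390, adjusted p = 0.000343). The flowering genes FPF1 and FLP1 were 199 times (35.4 to 7870) and 186 times lower (33.2 to 7390; adjusted p = 0.000419 and 0.000109). For 34% of tested genes the 3 libraries of each group did not overlap, where chance gives 10%. The total was 2087 without Col-0 replicate 2 and 2097 without Col-0 replicate 3, the number higher was 783, 802 and 804 without 35S:rMYB83 replicate 2, Col-0 replicate 2 and 35S:rMYB83 replicate 3, and the number lower was 1223 without Col-0 replicate 3. Scaling by library totals alone moved the median of all genes by -0.103 and gave 842 higher and 2771 lower.

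Most genes that changed in both lines changed in the same direction. In total 2421 genes changed in both lines against wild type, 929 higher in both, 1461 lower in both and 31 in opposite directions. If the lists were independent, 152.1, 255.8 and 397.1 genes would be shared in these classes. Genes higher in both included AT5G63250 for an X8 domain protein (0.227 ± 0.0406 CPM in wild type, 4.35 ± 0.927 in 35S:miR858 and 2.91 ± 0.138 in 35S:rMYB83, SD, n = 3; adjusted p = 4.15e-05 and 0.000167). Genes lower in both included NRT2.5, the cupin gene AT5G38910, the RWP-RK gene AT3G59580 (-7.29 in 35S:miR858, adjusted p = 0.000176) and AT4G01390, a TRAF-like gene 238 times lower in 35S:miR858 (42.4 to 9450) and 209 times lower in 35S:rMYB83 (37.2 to 8270; adjusted p = 5.86e-05 and 0.000121). Of the 31 opposite genes, 28 were lower in 35S:miR858 and higher in 35S:rMYB83, 3 were the reverse, and all 31 also passed the direct test between the lines. As these genes were picked for opposite changes, a pass of the direct test was likely beforehand and adds little. AT5G66670, for a DUF677 protein, had 6.80 ± 0.475 CPM in wild type, 1.73 ± 0.351 in 35S:miR858 and 19.3 ± 1.47 in 35S:rMYB83 (SD, n = 3; adjusted p = 9.54e-05 and 0.00024 against wild type). The regulator of phosphate signalling SPX1 stood at -1.44 and 1.44 on the log2 scale (SE 0.40 and 0.36, adjusted p = 0.0253 and 0.022), and KNAT7 at -0.74 and 0.80 (adjusted p = 0.00721 and 0.00627). The 3 reverse genes were the amino acid exporter family gene UMAMIT27 (0.88 and -0.93, adjusted p = 0.00421 and 0.00781), the meristem receptor kinase CLV1 (0.79 and -0.64, 0.00393 and 0.0173) and the indole glucosinolate methyltransferase gene IGMT4 (0.31 and -0.72, 0.0453 and 0.00154).

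Across all tested genes the fold changes of the lines had a Pearson correlation of 0.765 and a covariance of 0.434, and 76.6% had the same sign. In 40 simulations of unchanged groups against the same 3 wild-type libraries the medians were 0.482, 0.0378 and 65.9%, and the highest covariance was 0.0418. With 3 shared controls the wild-type libraries could not be split into separate sets, so part of the excess of shared genes over independent lists may come from the shared controls. The covariance lay 0.397 above the simulated median, which already includes them. The genes changed in both numbered 1556 without Col-0 replicate 2, and the opposite genes 17, 19 and 20 without Col-0 replicate 3, Col-0 replicate 2 and 35S:rMYB83 replicate 1. Single left-out libraries ended the call of SPX1 against wild type in 35S:miR858 (adjusted p = 0.0718, 0.0614 and 0.0842 without Col-0 replicate 1, 35S:miR858 replicate 2 and 35S:miR858 replicate 3). In 35S:rMYB83 they ended it too (0.0784, 0.0815, 0.0658 and 0.0580 without Col-0 replicate 2, Col-0 replicate 3, 35S:rMYB83 replicate 1 and 35S:rMYB83 replicate 2). They also ended that of CLV1 in 35S:rMYB83 (0.0631 and 0.0539 without Col-0 replicate 3 and 35S:rMYB83 replicate 1). The call of IGMT4 in 35S:miR858 ended likewise (0.0831, 0.149, 0.135, 0.102 and 0.0635 without Col-0 replicate 1, Col-0 replicate 2 and 35S:miR858 replicate 1, 2 and 3).

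**Figure D3:**
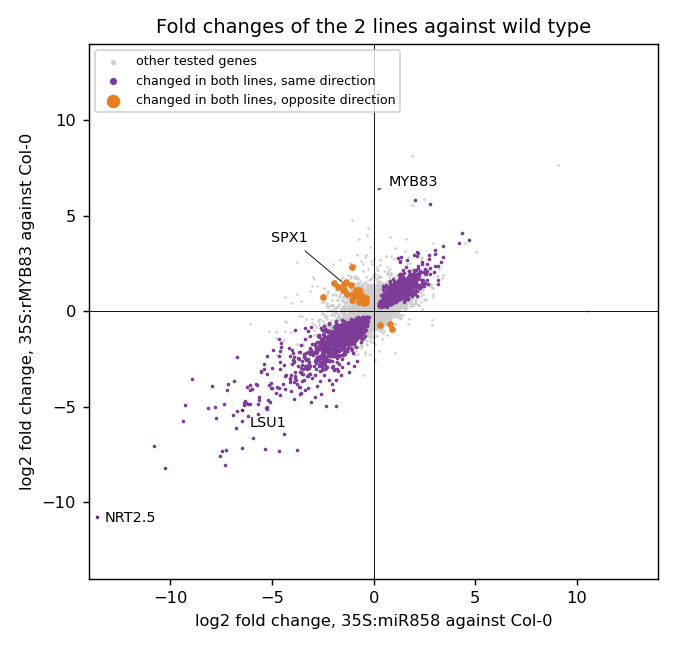
Log2 fold changes against Col-0 of all tested genes in 35S:miR858 and 35S:rMYB83, with genes past the threshold in both lines in colour.

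Compared directly, 7 flavonoid enzymes, 7 lignin enzymes and 5 wall regulators were higher in 35S:rMYB83 than in 35S:miR858. Of 13 tested flavonoid enzymes 7 rose and 6 did not pass (11 rose adjusted over the list alone). Members averaged 1.65 (adjusted p = 9.3e-10, and adjusted p = 0.52 with an estimated correlation). FLS1 of flavonol synthesis stood at 105 ± 28.9 CPM in 35S:rMYB83 and 15.9 ± 12.5 CPM in 35S:miR858 (SD, n = 3; log2 2.73, SE 0.44, adjusted p = 0.00837). The flavonol glucosyltransferase UGT78D2 and 4CL3 were higher by 1.64 and 2.34 (adjusted p = 0.00432 and 0.00847). MYB12, an activator of these enzymes, was higher by 1.76 (SE 0.29, adjusted p = 0.0102). It was 1 of 4 tested miR858 targets, of which 3 did not pass (2 rose adjusted over the list alone). Mean change over the list was 0.83 (adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation), with MYB42 at 1.27, MYB20 at 0.54 and MYB13 at 0.03 (adjusted p = 0.095, 0.259 and 0.983). Of 22 lignin enzymes 7 rose and 15 did not pass (13 rose adjusted over the list alone). The mean over these genes was 0.45 (adjusted p = 5.1e-06, and adjusted p = 0.79 with an estimated correlation), with 4CL1 at 1.01, CCR1 at 0.75 and the cinnamate hydroxylase C4H at 0.79 (adjusted p = 0.00567, 0.00792 and 0.0118). Of 23 wall regulators 5 rose and 18 did not pass (6 rose adjusted over the list alone). The mean of the members was 0.57 (adjusted p = 5.1e-06, and adjusted p = 0.52 with an estimated correlation). KNAT7 was at 56.1 ± 7.28 against 19.4 ± 2.09 CPM and MYB63 at 12.5 ± 3.43 against 4.19 ± 1.01 CPM (SD, n = 3; adjusted p = 0.00156 and 0.00693), and MYB43 and the phenylpropanoid repressor MYB4 were higher by 1.39 and 1.25 (adjusted p = 0.00294 and 0.00512). Of 23 cellulose, xylan and xylem genes 1 rose and 22 did not pass (6 rose adjusted over the list alone). List-wide the mean came to 0.40 (adjusted p = 0.00052, and adjusted p = 0.94 with an estimated correlation), CTL2 of cellulose deposition at 1.48 (adjusted p = 0.014). DESeq2 called 13 lignin enzymes and 4 cellulose, xylan and xylem genes that rose. The call for CTL2 was lost without 35S:miR858 replicate 2 or 35S:rMYB83 replicate 2 (adjusted p = 0.0506 and 0.0571). The lignin enzymes that rose numbered 4 without 35S:miR858 replicate 1 and 3 without 35S:miR858 replicate 2, 35S:miR858 replicate 3, 35S:rMYB83 replicate 1 or 35S:rMYB83 replicate 2, and the flavonoid enzymes 4 without 35S:rMYB83 replicate 2. With fry in 1 direction the lignin list had adjusted p = 0.10 and the cellulose, xylan and xylem list 0.31.

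The expansin and phosphate starvation lists also passed in this comparison. Of 13 expansins 6 rose, 1 fell and 6 did not pass (7 rose and 3 fell adjusted over the list alone). Across the list the mean was 0.69 (adjusted p = 0.016, and adjusted p = 0.52 with an estimated correlation), with EXPA15 at 142 ± 29.2 against 24.9 ± 2.48 CPM (SD, n = 3) and EXPA4 and EXPB3 at a log2 of 1.25 and 1.42 (adjusted p = 0.00111, 0.00184 and 0.00392). Of 9 phosphate starvation genes 1 rose and 8 did not pass (5 rose adjusted over the list alone). Members averaged 1.02 (adjusted p = 0.00012, and adjusted p = 0.52 with an estimated correlation), SPX1 at 2.88 (adjusted p = 0.00442), and DESeq2 called 6 that rose. Without 35S:rMYB83 replicate 1 or 35S:rMYB83 replicate 3 the phosphate genes that rose numbered 2. Salicylic acid genes passed as a list in the other direction, with 1 of 12 that fell (1 adjusted over the list alone). The mean of the members was -0.45 (adjusted p = 0.027, and adjusted p = 0.86 with an estimated correlation), SAG101 at -0.77 (adjusted p = 0.00792). The list gave adjusted p = 0.171 and 0.0545 without 35S:miR858 replicate 2 and 35S:rMYB83 replicate 3. It gave 0.153 with no filter, 0.244 with the green covariate and 0.26 with fry in 1 direction.

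For green shoot, hypoxia, touch and clock genes the list test passed in the direct comparison, while almost no member passed the edgeR test. Median log2 values were 0.97, 0.95, -0.73 and 0.52 (adjusted p = 0.029, 0.029, 0.044 and 0.03; adjusted p = 0.99, 0.94, 0.94 and 0.79 with an estimated correlation). The clock gene GI was the 1 member of these lists that rose (1 adjusted over the list alone), at 216 ± 53.9 against 125 ± 16.0 CPM (SD, n = 3; adjusted p = 0.0395, and 0.133 at most with 1 library left out). Adjusted over the list alone 1 touch gene fell, and the smallest p in the other lists belonged to LHCB2.1 of the antenna (2.34, adjusted p = 0.283), HB1 of hypoxia (0.91, 0.241) and TCH3 of touch (-1.04, 0.094). At an unadjusted p under 0.05 edgeR gave 0, 1 and 3 members of the green shoot, hypoxia and touch lists, and DESeq2 called 0, 0 and 1. Without 35S:miR858 replicate 1, 6 hypoxia genes rose, without 35S:rMYB83 replicate 3, 2 clock genes rose, and without 35S:miR858 replicate 3, 1 touch gene fell. With fry in 1 direction the green shoot, hypoxia, touch and clock lists had adjusted p = 0.65, 0.34, 0.40 and 0.19. With the green covariate the green shoot and clock lists had 0.991 and 0.116, without Col-0 replicate 1 and 35S:rMYB83 replicate 1 together 0.673 and 0.205, and on library totals the green shoot list had 0.0816. The green shoot list had adjusted p = 0.202 without 35S:miR858 replicate 2 and 0.896 without 35S:rMYB83 replicate 1. The hypoxia list had adjusted p = 0.0837, 0.107, 0.0687 and 0.0589 without 35S:miR858 replicate 2, 35S:miR858 replicate 3, 35S:rMYB83 replicate 2 and 35S:rMYB83 replicate 3, and the touch list 0.103, 0.171, 0.0804 and 0.101 without 35S:miR858 replicate 1, 35S:miR858 replicate 2, 35S:rMYB83 replicate 2 and 35S:rMYB83 replicate 3. The clock list had 0.0563, 0.269 and 0.0525 without 35S:miR858 replicate 1, 35S:rMYB83 replicate 1 and 35S:rMYB83 replicate 2, and GI lost its call without any 1 of 35S:miR858 replicate 1, 35S:miR858 replicate 2, 35S:miR858 replicate 3, 35S:rMYB83 replicate 1 and 35S:rMYB83 replicate 2.

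In the remaining lists the direct test passed few genes. Iron deficiency genes had 1 of 15 that rose, F6'H1 of coumarin synthesis at 0.94 (adjusted p = 0.00573; 1 adjusted over the list alone; list adjusted p = 0.43). Phloem genes had 1 of 13 that fell, FTIP1 at -0.71 (adjusted p = 0.0106; 1 adjusted over the list alone; list adjusted p = 0.66). No member passed the edgeR test in the jasmonate, glucosinolate, auxin, cytokinin, root hair, endodermis, meristem and heat shock lists (list adjusted p = 0.59, 0.52, 0.62, 0.97, 0.68, 0.43, 0.31 and 0.89). Their smallest p belonged to the jasmonate lipoxygenase LOX2 (4.38, adjusted p = 0.082), CYP83B1 of indole glucosinolates (-0.50, 0.0751), GH3.5 of auxin conjugation (-0.33, 0.265), the response regulator ARR6 (0.32, 0.162), RSL4 of root hairs (-0.37, 0.313), FAR4 of suberin (0.59, 0.279), the cyclin CYCA1;1 (0.45, 0.277) and the chaperone HSP18.2 (-1.01, 0.295). At an unadjusted p under 0.05 edgeR gave 6, 6, 1, 1, 0, 0, 1 and 0 members of these 8 lists, and DESeq2 called 1, 3, 0, 0, 0, 0, 0 and 0. Without 35S:miR858 replicate 1, 2 root hair genes rose. Without 35S:miR858 replicate 3, 1 jasmonate gene fell, and the jasmonate and iron deficiency lists had adjusted p = 0.00625 and 0.038. For the jasmonate list the mean was 0.17, the median -0.24 and the direction of the test down.

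In all, 789 of 19496 genes (4%) differed between the lines, 488 higher and 301 lower in 35S:rMYB83, with 283 and 98 at a fitted fold of at least 2. Beside MYB83 the genes with the largest excess in 35S:rMYB83 included the CCT motif gene AT2G33350, 107 times higher (18.8 to 4280, adjusted p = 0.00442). Genes lower in 35S:rMYB83 included the miR858a precursor, at least 160-fold lower against the floor over the group, the amino acid export gene GDU5 (log2 -3.57, SE 0.43) and AT2G48090, for an uncharacterized protein (-2.85, SE 0.28; adjusted p = 0.00193, 0.00246 and 0.00145). For 24.8% of tested genes the 3 libraries of each group did not overlap, where chance gives 10%. DESeq2 called 1268 genes, 703 higher and 565 lower. The total was 322, 365 and 409 without 35S:miR858 replicate 2, 35S:rMYB83 replicate 2 and 35S:rMYB83 replicate 1, and the number higher 238, 263, 310 and 313 without 35S:miR858 replicate 2, 35S:rMYB83 replicate 2, 35S:miR858 replicate 3 and 35S:rMYB83 replicate 1. The number lower was 84, 96, 102 and 180 without 35S:miR858 replicate 2, 35S:rMYB83 replicate 1, 35S:rMYB83 replicate 2 and 35S:rMYB83 replicate 3.

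**Figure D4:**
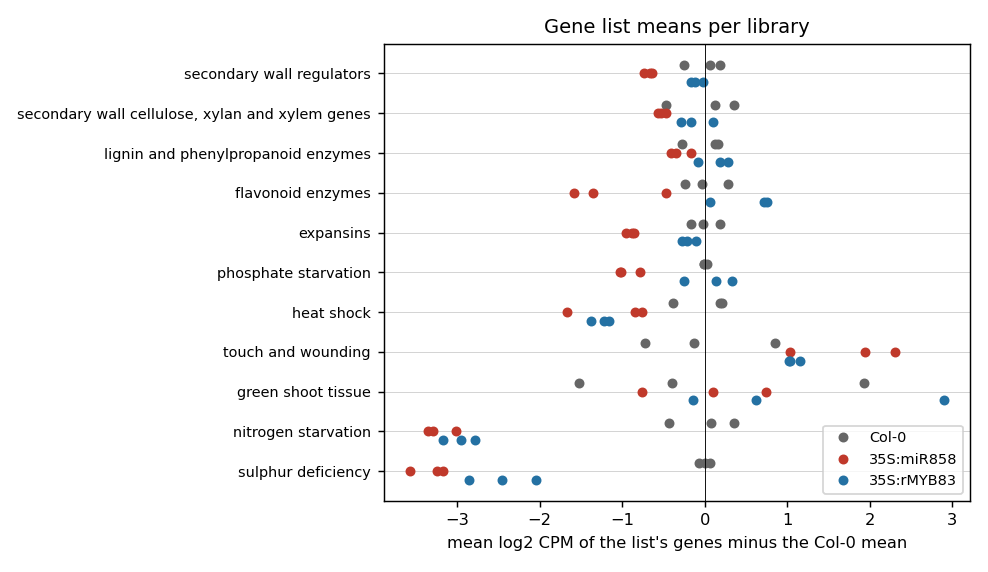
Mean log2 CPM of the genes of 11 lists in each of the 9 libraries, minus the Col-0 mean.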

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

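The tests of shared-control noise and of nitrogen and sulphur genes, the green marker covariate and the fit without 2 libraries were chosen only after the results were seen.

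The direct test of the difference drew attention to 3 results: 31 genes that changed in opposite directions in the lines, the lignin list with a mean of 0.45 and the flavonoid list with a mean of 1.65 in 35S:rMYB83 against 35S:miR858. Lists were taken where the means against wild type had opposite signs, the direct test passed and at least 3 members passed the gene test. Target MYB, phosphate starvation and salicylic acid lists met the first 2 conditions but not the third. Against wild type neither the lignin nor the flavonoid list passed in 35S:rMYB83 in the fit without a block (adjusted p = 0.68 and 0.08), and with the replicate number as a block the flavonoid list passed (adjusted p = 0.0354). Between the lines the list tests had adjusted p = 5.1e-06 and 9.3e-10, and adjusted p = 0.79 and 0.52 with an estimated correlation. Of 22 lignin and 13 flavonoid enzymes 7 each passed the gene test.

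The fold changes of both lines against wild type went the same way at 2390 genes, and 1 of 100 assignments of the 9 libraries, the real one, gave as many. The highest other gave 1927 and kept the 3 wild-type libraries together, so the structure followed wild type against the rest. Their covariance of 0.434 lay above all 40 simulations of shared-control noise (highest 0.0418), and with the green score as covariate the folds kept a median ratio of 0.999 in 35S:miR858 and 0.964 in 35S:rMYB83, which argues against both as the whole cause. A lower supply of nitrogen and sulphur to the wild-type plants may account for part of it, since list members not seen when the lists were written had means of -2.14 or lower in both lines, but supply and genotype cannot be told apart because the labels do not give the medium. Harvest time or handling of the wild-type plants cannot be told apart from genotype either, because the labels do not give them. Of 11 clock genes, fixed as markers of these, 4 rose and 5 fell in 35S:miR858 and 4 rose and 4 fell in 35S:rMYB83. Of all tested genes 25.1% and 16.4% changed. Of 5 heat shock genes 3 fell in each line, and of 6 touch genes 5 and 1 rose. Of 8 hypoxia genes 2 and 0 fell. An effect shared by both transgenes stays open as an untested biological explanation.

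Flavonoid enzymes were higher in 35S:rMYB83 than in 35S:miR858, and with the green score as covariate the list mean was 1.52, which argues against green tissue as the whole cause. Lower flavonol MYB factors in 35S:miR858 may contribute. Of MYB11, MYB12 and MYB111, only MYB12 (1 of 1 tested) differed between the lines by more than 2 SE. A rise in 35S:rMYB83 alone could also give such a difference. MYB12 had 11, 13.2 and 12.4 CPM in Col-0 and 29.9, 29.7 and 15.5 in 35S:rMYB83. In 35S:miR858 it had 9.6, 7.81 and 4.73 CPM and did not pass against wild type (log2 -0.73, edgeR adjusted p = 0.101). The other 2 had too few counts, so this stays open. A direct effect of MYB83 on these enzymes, which the genotypes allow, was not tested.

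Green shoot transcripts varied within genotypes. Between the green score and the library total r was -0.34 (permutation p = 0.37, n = 9), which 9 libraries are too few to read. Col-0 replicates 1 and 2 had 10400372 and 10648857 gene counts but green shares of 0.46% and 0.0898%, which argues against depth as the whole cause for these libraries. Shoot tissue in the harvest and greening of the roots themselves could both be sources and were not told apart. The score had r = 0.69 with the CPM of 9 leaf and stomatal identity genes (permutation p = 0.04, adjusted over 2 relations 0.08). Without Col-0 replicate 1 and 35S:rMYB83 replicate 1 this r was 0.20, and that with the library total 0.29. Of the counts of the 9 genes, AT1G02205 alone held 164 of 185 in Col-0 replicate 2 and 43 of 46 in Col-0 replicate 3. In Col-0 replicate 2, with a green score of 4.96, the 9 genes came to 16.8 CPM. That was above the 13 CPM of Col-0 replicate 1, with a score of 7.29, so AT1G02205 worked against the r of 0.69 there. The relation of the other genes to the score was not tested.

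For the numbers of genes changed, 1 of 10 splits gave as many in each comparison, the real one, with 0 as the highest other against 4900, 3203 and 789; 10 splits are too few for a share under 0.05. For the numbers of lists past the threshold, adjusted within each comparison, 4, 10 and 2 of 10 splits gave as many as the real 8, 1 and 12, with 12, 12 and 13 as the highest others, so other splits reached as many lists; 10 splits are too few for a share under 0.05. Against the real 1, the 12 lists came from Col-0 replicate 1 with 35S:rMYB83 replicates 1 and 2 on one side, which points to a structure of the samples beside genotype. The 3 other splits that parted all 3 pairs of Col-0 and 35S:rMYB83 gave 4, 4 and 8 lists and 0 genes, and the 6 that parted 1 pair gave 2 to 12 lists and 0 genes.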

How the results depend on the processing

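The fits without Col-0 replicate 1 and 35S:rMYB83 replicate 1 together, with the green score as covariate, and on library totals without scaling were tests chosen only after the results were seen; the others were planned. No result reversed. Of 341 results for named genes, 340 kept their side of the threshold with RLE size factors, 327 with DESeq2, 330 with the green covariate, 322 on library totals and 308 without the 2 libraries; with 1 library left out 1817 of 2046 did. DESeq2 gave 1268 genes for the direct comparison, 565 of them lower; without the 2 libraries 179 were lower. Library totals gave 1355 higher and 4148 lower genes in 35S:miR858 and 842 higher in 35S:rMYB83. With 1 library left out, genes changed in 35S:miR858 ranged from 3468 to 5146 (1493 to 2277 higher, 1975 to 2869 lower), in 35S:rMYB83 from 2087 to 3791 (783 to 1537 higher, 1223 to 2254 lower), and between the lines from 322 to 684 (238 to 464 higher, 84 to 279 lower). Genes changed in both lines ranged from 1556 to 2863, in the same direction from 1537 to 2831 and opposite from 17 to 34. Lists past the threshold ranged from 3 to 8, 1 to 5 and 8 to 13. Camera with an estimated correlation passed 0 lists in each comparison, where the preset passed 7, 2 and 12 and fry in 1 direction 7, 2 and 5; fry mixed passed 18, 13 and 7. For 35S:rMYB83 against wild type the lists numbered 4 with the replicate block (flavonoid enzymes and green shoot tissue added), 5 without the 2 libraries, 1 with the green covariate and 4 on library totals. With the green covariate they numbered 6 in 35S:miR858 (lignin lost) and 9 between the lines (salicylic acid, green shoot and clock lost). The loss of the green shoot list was fixed in advance, because its own markers make up the covariate. Libraries of the same number correlated in their deviations at -0.06, 0.12 and -0.26 between Col-0 and 35S:miR858 and -0.10, 0.31 and -0.13 between the lines, where 1 and 2 of 6 libraries correlated best with their own number, so they shared only a number there. With the replicate block 5002 genes changed in 35S:miR858, 3315 in 35S:rMYB83 and 924 between the lines. In 35S:miR858 the phosphate starvation list (adjusted p = 0.0328) and MYB12 (adjusted p = 0.0426) passed with the block. IGMT4 and UPM1 did not (adjusted p = 0.0626 and 0.0556), and between the lines MYB42 passed (adjusted p = 0.0481). In 35S:rMYB83 the block changed no other call of a gene printed for that comparison beside those of TCH3, HB1 and NIR1. The cause of these differences was not tested, except that leaving out a library leaves fewer samples. Depth limited genes of few counts such as MYB11 and MYB111.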

Other observations

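The lists in this part were chosen after the results were seen, as were their tests; the tests of predicted miR858 sites were planned.

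Genes that plants raise when sulphur is short were lower in both overexpression lines than in wild type. All 15 tested sulphur deficiency genes fell in 35S:miR858 and in 35S:rMYB83, with medians of -2.43 and -1.81 on the log2 scale, also with BGLU28 at its bound. Values of 4 of them, among them LSU1, APR1 and GGCT2;1, had been seen before the list was written. The other 11 had medians of -2.43 and -1.59 (list adjusted p = 2.8e-10 and 2.9e-10, and adjusted p = 0.054 in both with an estimated correlation). BGLU28, among the largest falls in 35S:miR858, was 1 of these 11, so the test is not independent of the results that led to the list. LSU1, for a small protein of sulphur starvation, stood at -6.48 and -5.15 on the log2 scale (SE 0.38 and 0.34, adjusted p = 1.79e-05 and 4.19e-05). The sulphate reductase APR1 stood at -2.31 and -1.58 (adjusted p = 1.59e-06 and 1.73e-05). For the root sulphate transporter SULTR1;1 the values were -3.30 and -3.37, and for GGCT2;1 of glutathione breakdown -7.22 and -4.10 (adjusted p = 4.11e-05 and 7.9e-05, 2.63e-06 and 1.73e-05). Between the lines 3 of these genes were higher in 35S:rMYB83, APR1 at 0.73, the LSU1 relative LSU2 at 2.91 and GGCT2;1 at 3.11 (adjusted p = 0.00277, 0.00462 and 0.00402; for the 11 genes list adjusted p = 0.00039, and adjusted p = 0.17 with an estimated correlation).

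Of 13 tested nitrogen starvation genes 12 fell in both lines, with medians of -2.84 and -2.57, also with NRT2.5 at its bound. Values of 4 of them, among them NRT2.5 and NF-YA2, had been seen before the list was written. Of the other 9, 8 fell in both lines, with medians of -1.81 and -1.39 (list adjusted p = 9.4e-07 and 3.2e-07, and adjusted p = 0.054 in both with an estimated correlation). The exception was the nitrate transporter family gene NRT2.6 (0.21 and 0.34, adjusted p = 0.869 and 0.80). In 35S:rMYB83 the call of NF-YA9, 1 of the 8, was lost without Col-0 replicate 1, 2 or 3 (adjusted p = 0.0542, 0.0831 and 0.0681). It was also lost without 35S:rMYB83 replicate 2 or 3 (0.103 and 0.0692). NF-YA2, for a transcription factor subunit of nutrient responses, dropped from 210 ± 53.1 to 12.1 ± 1.63 and 18.5 ± 1.08 CPM (SD, n = 3; adjusted p = 7.54e-06 and 1.73e-05), and the ammonium transporter AMT1;1 stood at -3.30 and -2.48 (adjusted p = 0.000462 and 0.00246). Between the lines the 9 genes had list adjusted p = 0.12. Of 11 nitrate-induced genes 6 rose and 1 fell in 35S:miR858 and 6 rose in 35S:rMYB83 (list adjusted p = 0.012 and 1.2e-05, and adjusted p = 0.38 and 0.17 with an estimated correlation). In 35S:miR858 the calls of NIR1, UPM1 and LBD37 were lost without Col-0 replicate 3 (adjusted p = 0.0806, 0.0619 and 0.0503) and without 35S:miR858 replicate 3 (0.0673, 0.135 and 0.0577). Those of NIR1 and UPM1 were also lost without Col-0 replicate 2 (0.0725 and 0.0961) and without 35S:miR858 replicate 2 (0.106 and 0.13). In 35S:rMYB83 those of NIR1 and LBD37 were lost without Col-0 replicate 3 (0.141 and 0.0613) and without 35S:rMYB83 replicate 2 (0.166 and 0.0634). That of NIR1 was also lost without Col-0 replicate 2 (0.133), without 35S:rMYB83 replicate 3 (0.126) and with the replicate number as a block (0.0742). The nitrate response factors HRS1 and LBD38 rose by 1.16 and 1.66 in 35S:miR858 and by 1.17 and 1.67 in 35S:rMYB83 (adjusted p = 0.000683 and 0.000362, 0.00118 and 0.00064). NRT1.1, the nitrate sensor and transporter, stood at 0.20 and 2.14 (adjusted p = 0.638 and 0.000716) and differed between the lines by 1.95 (adjusted p = 0.00409). Between the lines 2 of the 11 rose, and the list median was 0.05 (mean 0.38, adjusted p = 0.034, and adjusted p = 0.40 with an estimated correlation). Of these 2, NIA2 lost its call without 35S:miR858 replicate 1 or 2 (adjusted p = 0.0691 and 0.08) and without 35S:rMYB83 replicate 1 or 2 (0.0879 and 0.0747).

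A hypothesis was that transcripts with a predicted miR858 site are lower as a set in 35S:miR858. The 32 tested genes with a site penalty of at most 5 had a median of -0.30 against wild type, at percentile 0.89 of 10000 random lists, with 10 that fell and 3 that rose, which is in line with it. The 55 tested MYB genes without such a site had the same median of -0.30, so membership of the MYB family may account for it as well. The 8 genes with a penalty of at most 4 had a lower median of -0.53 (percentile 1.72) and 0.35 between the lines (percentile 98.7). Their difference from MYB genes without a site was not tested. Medians of the genes with a site were -0.13 in 35S:rMYB83 against wild type (percentile 8.59) and 0.19 between the lines (percentile 99.1), where MYB genes without a site had -0.17 and -0.09.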
